A study of Mus musculus with 6 samples.

How the data were processed

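Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in ATDC5 cells, a mouse line of chondrocyte precursors. Per the labels' protocols, cells were spotted as dense droplets, left to attach, and differentiated in medium with beta-glycerophosphate and ascorbate-2-phosphate, and were collected at day 0, day 3 and day 10. Per the labels, each time point has 2 biological replicates described as independent, and the reads were single-end. The 6 libraries form 3 groups named Day0, Day3 and Day10, each with 2 libraries. Groups and replicate numbers were taken from the sample titles.

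The deposited data are 1 narrowPeak list per library, so peaks were listed for each library alone and not on pooled libraries. Trim Galore, a read trimmer, is named in the submitters' processing notes. The aligner, the peak caller and their settings are not given in the sources used here, and neither is any shift of the reads for the Tn5 cut site. Each row of a deposited list holds a start, an end, a summit, an integer score, a fold ratio over background, a -log10 p and a -log10 q. All of these values are the authors' own. In the deposited lists the score follows the -log10 q, and the fold ratio takes evenly spaced values. From the spacing of the deposited fold ratios, each was found to be (pileup + 1) / (background + 1) with a single background per library. The recovered pileups were whole numbers within 0.001 in 100% of the peaks of each library. The authors' -log10 p matched the Poisson tail of that pileup within 0.001 in 100% of the peaks for which the tail could be computed. The recovered background was 0.7165 and 0.7308 in the Day0 libraries, 0.7985 and 0.7984 in the Day3 libraries, and 1.0845 and 1.1515 in the Day10 libraries. The smallest listed width was 88 and 90 bases at Day0, 87 and 88 at Day3, and 68 and 72 at Day10. If that width is the length to which reads were extended, background divided by width gives a depth relative to Day0 replicate 1 of 1.0 for Day0 replicate 2, 1.13 and 1.11 for the Day3 libraries and 1.96 for both Day10 libraries. These depths are estimates from the peak scores. Total read numbers were not used here.

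Because of this formula, the order of peaks by -log10 p and by fold is the same, with 0 peaks placed differently in any library. Pileups are whole numbers, so many peaks tie: between 1666 and 2061 peaks per library share the fold found at rank 50000. The largest recovered pileup at Day10 was 136 and 144, which is 2 times the smallest width, as when each position is counted once per strand. It was 166 and 172 at Day0 and 173 and 174 at Day3, in each library somewhat below 2 times its smallest width. Strong peaks are therefore likely to be compressed in these values.

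Genome build. The submitters' processing notes name mm10. The lists hold scaffold names that belong to GRCm39, and the gene table at hand, for GRCm38.p6, did not match them: a strong summit lay within 500 bases of an end of 4.5% to 4.8% of its 21883 protein-coding genes, and of 2.9% to 3.0% when the genes were shifted by 1 megabase. Positions are therefore given as the lists give them, read as GRCm39 and counted from 1. No annotation or genome sequence of that build was used here, coordinates were not converted, and regions were not assigned to genes. The planned gene lists, named genes, promoter shares, transcription factor motifs and repeat filter need an annotation or genome of that build and were not run.

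Comparisons. All rules in this paragraph were fixed before the data were examined. Chromosomes 1 to 19, X and Y were used. Within each library, peaks were ranked by the authors' -log10 p, then by fold, then by position. Since the lists differ in length, the 50000 strongest peaks of each library were compared. Regions were windows of 501 bases centred on the summits of those peaks, with overlaps resolved in favour of the better rank, which gave 78698 regions. The rank of a region in a library is that of its best peak with a summit in the window. A region was called gained on the later of 2 days when its rank was 50000 or better in both libraries of that day, and worse than 100000 or not listed in both libraries of the earlier day. Lost regions met the mirrored rule, and kept regions ranked 50000 or better in all 4 libraries. No p-value was computed from 2 against 2 libraries. The count was set instead beside those from the 2 other ways of splitting the same 4 libraries into pairs. Each such split puts 1 library of each day on both sides, so it can only call regions on which the replicates disagree. These counts thus measure disagreement between replicates and do not estimate how many calls variation between cultures would give. Similarity was the Jaccard index of the bases covered by the 50000 strongest peaks, with an exact permutation test over the 15 ways of pairing 6 libraries. The regions named in the text are the 10 gained and 10 lost regions per comparison with the best summed rank in the libraries that hold them.

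A further rule was added after the data were seen. Under it a library holds a region when any listed peak overlaps the window by 1 base or more, wherever its summit lies. Regions called by the summit rule and by this overlap rule are described as passing both rules. Regions named from that set were chosen after their values were seen, in order of summed rank. The rank classes taken from 1 library and the overlap of calls among regions that the Day0 ranks allow were added after the data were seen. The test of 1-megabase bins and the comparison of chromosomes were also added after the data were seen. The first used the hypergeometric distribution over bins with 10 or more regions and the second used Fisher's exact test, each with Benjamini-Hochberg adjustment. Their p-values are across regions, which are not independent replicates.

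Replicates were compared before use. Over regions with a recovered pileup of 10 or more in both libraries, the squared difference between the libraries of a day, divided by that of Poisson counts, was 0.239 at Day0, 0.245 at Day3 and 0.211 at Day10, and between 2.045 and 5.258 for libraries of different days. The 2 libraries of each day thus differed by less than Poisson noise. Compressed pileups make such a test unreliable here. Peaks with identical start and end made up 0.062% to 0.084% of the lists within a day and 0.007% to 0.055% between days. The 2 libraries were kept apart as the labels give them, both values are given, and no SD is computed from them. Each rule needs both libraries of a day, and the spread within a day may be technical.

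The rule was tested on simulated data with Poisson counts over 384746 windows, with 200 windows raised and 200 lowered, in 10 draws. Counts were scaled by each library's recovered background, not by the depth estimated above. The Day0 pileups served as the truth for all libraries, without saturation, and the raised windows were weak ones among those listed at Day0. For Day10 versus Day0, 0.0% of the windows raised and 0.2% of those lowered by 2-fold were called, 40.1% and 27.4% at 4-fold, and 71.8% and 77.6% at 8-fold. For Day3 versus Day0 the shares were 38.7% and 27.0% at 4-fold and 71.8% and 76.4% at 8-fold. In this simulation the rule thus left out most smaller changes. The real Day10 lists are longer and their folds at the rank cutoffs differ, so these shares may not hold for them. Alternatives changed the number of peaks compared, the gap between ranks, the authors' threshold, the form of a region, the overlap required, the order of ties, the replicate block and the libraries included. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 20.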

Results

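ATAC-seq peak lists were compared for ATDC5 mouse chondrocyte precursors at day 0, day 3 and day 10 of differentiation, with 2 libraries per day. ATDC5 cells are grown as precursors and form cartilage-like cultures when differentiated. The Day0 libraries listed 164642 and 164960 peaks, the Day3 libraries 177751 and 177111, and the Day10 libraries 381376 and 390100. On the assembled chromosomes these peaks covered 55.76 and 56.38 megabases at Day0, 61.44 and 61.14 at Day3, and 101.42 and 107.06 at Day10. Over the whole lists, the median fold and the median width were lowest at Day10. The median fold over background, the authors' own value, was 9.9 and 9.82 at Day0, 7.78 in both Day3 libraries, and 5.76 and 5.58 at Day10. The median width was 230 and 233 bases at Day0, 210 and 213 at Day3, and 161 and 166 at Day10.

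The length of a list can depend on depth and on the authors' threshold. The depth estimated from the peak scores, which takes the smallest width as the length of an extended read, was 1.96 times that of Day0 replicate 1 in both Day10 libraries, and 1.13 and 1.11 times in the Day3 libraries. The Day10 lists were 2.34 times as long as the Day0 lists on average, 1.52 times when only peaks with a -log10 q of 5 or more were counted, and 1.47 times at 10 or more. The Day3 lists were 1.08 times as long as the Day0 lists. At a -log10 q of 5 or more they were 0.9 times as long, and at 10 or more 0.94 times, so the direction turned. Regions below are called gained, lost or kept from equal numbers of the strongest peaks unless stated. Equal ranks do not stand for equal folds. The fold at rank 50000 was 16.89 and 17.33 at Day0, 14.46 and 15.01 at Day3, and 17.75 and 17.66 at Day10. At rank 100000 it was 7.57 and 7.51 at Day0, 6.67 and 7.23 at Day3, and 10.07 and 10.23 at Day10. A region lost at Day10 can thus keep a fold near 10, while a region gained against Day0 had to start lower. The 2 libraries of each day differed by less than Poisson sampling noise, but compressed pileups make that test unreliable. It cannot tell technical from biological spread. The spread may be technical, and both values are given. The Day10 libraries also had a smaller minimum peak width, 68 and 72 bases against 87 to 90 in the other libraries. No library of another day shares that property, so day 10 and any separate handling of its libraries cannot be told apart. Names inside the Day3 lists alone hold the word lysis, so day 3 and a separate handling at Day3 cannot be told apart either.

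The first question was whether the strongest open regions followed the day of differentiation. Among the 50000 strongest peaks, libraries of the same day shared the largest part of their covered bases. The Jaccard index was 0.834 between the Day0 libraries, 0.821 between the Day3 libraries and 0.817 between the Day10 libraries. Between days it averaged 0.657 for Day0 and Day3, 0.517 for Day3 and Day10, and 0.454 for Day0 and Day10. Of the 15 ways of pairing the 6 libraries, the pairing by day had the highest mean index, 0.824, and the next highest was 0.711. The one-sided exact permutation p was 0.067, the smallest that 15 pairings allow.

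**Figure D1:**
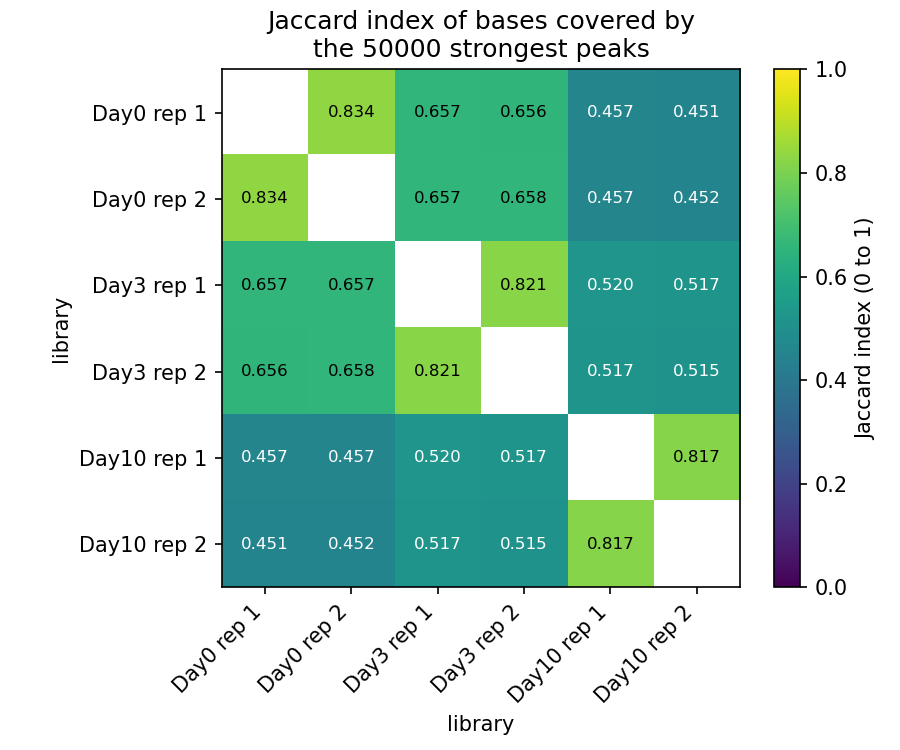
Jaccard index of the bases covered by the 50000 strongest peaks for each pair of the 6 libraries, on a scale from 0 to 1. Pairs of one day lie between 0.817 and 0.834, Day0 with Day3 near 0.657, and Day0 with Day10 near 0.454.

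The share of regions held on another day fell with rank. A region is counted here when any listed peak overlaps it. Of 4462 regions within the 5000 strongest in both Day0 libraries, 99.8% were within the 50000 strongest of both Day3 libraries and 97.3% within those of both Day10 libraries. Of 9646 regions whose poorer Day0 rank lay between 40000 and 50000, 54.8% were held at Day3 and 39.2% at Day10. In the other direction, 94.4% of the 4835 strongest Day10 regions were held at Day0, against 39.8% of the 9387 regions in the last rank class. From Day3 to Day10 the shares fell from 99.1% to 34.8% across the same rank classes. With the rank classes taken from Day0 replicate 1 alone, a comparison added after these shares were seen, Day0 replicate 2 held 99.8% of the first class, 98.5% of the class from 30000 to 40000 and 74.5% of the last. The Day10 libraries held 97.1% in each, then 51.0% and 51.3%, then 40.1% and 40.2%. Part of the decline in the last class is thus seen within a day. A region near rank 50000 also leaves after a small fall and a top region only after a large one, so these shares do not show that strong regions moved less.

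**Figure D2:**
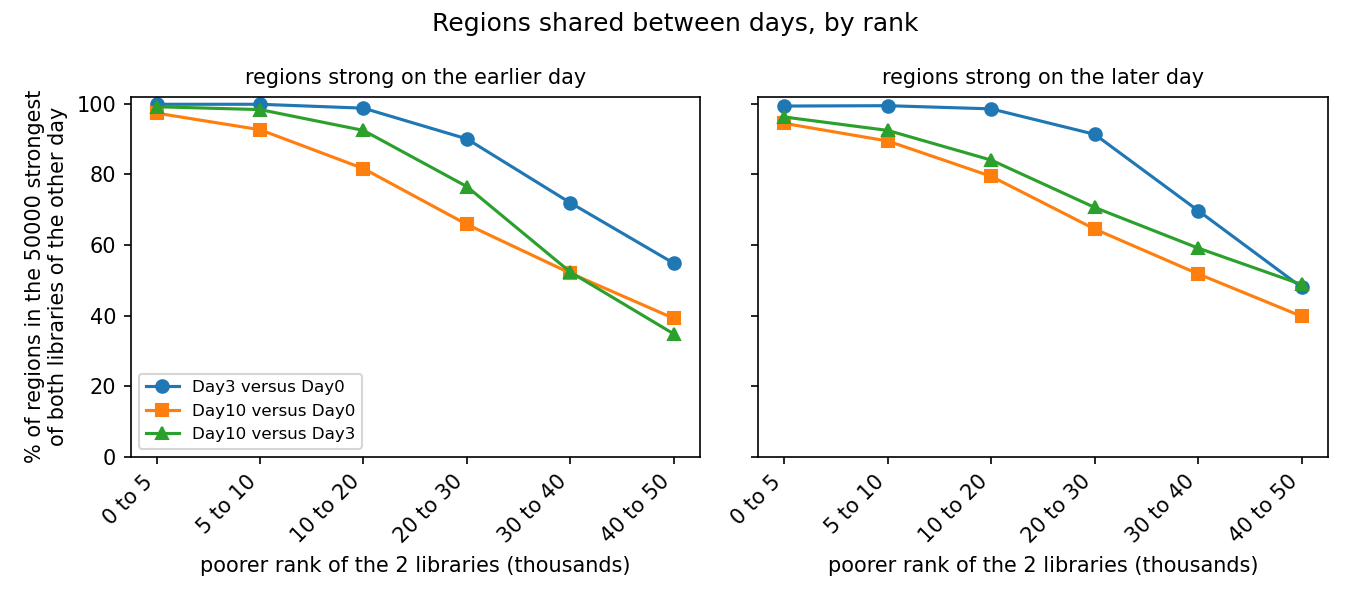
Percent of regions held by the 50000 strongest peaks in both libraries of the other day (y axis), by the poorer rank of the 2 libraries of the starting day in rank classes (x axis), for the 3 comparisons. From Day0 to Day10 the share falls from 97.3% in the first rank class to 39.2% in the last, and from Day0 to Day3 from 99.8% to 54.8%.

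Day3 was compared with Day0 to find regions that opened or closed early. By the summit rule, 923 of 78698 regions were gained, 1353 were lost and 35847 were kept. The other splits of the same 4 libraries, which can only call regions on which the replicates of each day disagree, gave 59 to 81 regions. Many of these calls were shifts of a summit within a peak present on both days: 46.0% of the gained and 65.0% of the lost regions were covered by one of the 50000 strongest peaks in both libraries of the other day. Regions that passed both rules numbered 427 gained and 404 lost, against at most 2 in the other splits under the overlap rule. The summit rule had fewer gained than lost regions and both rules together had more, so no direction is given for the balance at Day3.

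All 10 gained and all 10 lost regions named by the fixed rule for Day3 were of this covered kind. The strongest gained one lay on chromosome 14 from 20815932 to 20816432. It held a summit at ranks 249 and 465 at Day3, while peaks at ranks 2043 and 952 covered it at Day0 with their summits outside it. On chromosome 8, the window from 96534501 to 96535001 was gained and the neighbouring window from 96533950 to 96534450 was lost. At Day0 a peak ranked 338 and 923 overlapped both windows with its summit in the second. At Day3 a peak ranked 479 and 1345 overlapped both with its summit in the first. The windows on chromosome 7 from 44667099 to 44667599 and from 44666500 to 44667000 formed a similar pair. The strongest lost region, on chromosome 17 from 40154098 to 40154598, ranked 9 and 12 at Day0 and was covered at Day3 by a peak ranked 8 and 9.

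Among regions that passed both rules, named after their values were seen, the strongest gained at Day3 lay on chromosome 10 from 75427304 to 75427804. It ranked 110039 and 129785 at Day0, 16913 and 14526 at Day3, and 12492 and 12201 at Day10. A region on chromosome 5 from 25186725 to 25187225 ranked 100690 and 126057 at Day0, 19022 and 27764 at Day3, and 2380 and 3282 at Day10. A region on chromosome 8 from 18770716 to 18771216 had no listed peak in either Day0 library and ranked 29677 and 20368 at Day3. By contrast, the region on chromosome 8 from 73681743 to 73682243 ranked 19186 and 17972 at Day3 and 66193 and 75427 at Day10. The strongest lost region, on chromosome 4 from 47200184 to 47200684, ranked 13553 and 10812 at Day0 and 101147 and 110414 at Day3, and was not listed at Day10. On chromosome 5, the region from 111019772 to 111020272 ranked 18437 and 30565 at Day0 and was not listed in either Day3 library.

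Calls at Day3 lay near the rank of 50000 that the rule uses, which the rule itself favours. Gained regions that passed both rules had a median rank of 41457 and 41637 in the Day3 libraries, and 75.6% of them were listed in each Day0 library. Over all of them, with those not listed placed last, the median Day0 rank was 131404 and 131930. Lost regions, counted in the same way, had a median rank of 42467 and 43241 at Day0 and of 125409 and 124196 at Day3. Without Day3 replicate 2 the lost count by the summit rule was 2093, and without Day0 replicate 1 the gained count was 1400, each over 1.5 times the count with all libraries. Fewer conditions had to be met there, so these counts could only rise.

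Day10 was compared with Day0 to find the regions that differed at the end of the time course. By the summit rule 9436 regions were gained, 7879 were lost and 27453 were kept, and the other splits of the 4 libraries gave 29 to 60 regions. Regions that passed both rules numbered 8449 gained and 6285 lost, against 0 in the other splits under the overlap rule. The excess of gained over lost regions turned when no gap between ranks was required, with 15155 gained and 15324 lost.

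Of the 10 gained regions named by the fixed rule, 6 passed both rules. The region with the best ranks lay on chromosome 6 from 126748543 to 126749043. It ranked 319 and 200 at Day10, with an authors' fold of 46.1 and 47.9, and 139158 and 139671 at Day0. At Day3, a peak ranked 22542 and 24774 overlapped it with its summit outside. On chromosome 17, the region from 32012413 to 32012913 ranked 543 and 489 at Day10 and 92166 and 87265 at Day3, and was not listed at Day0. On chromosome 11, the region from 100578035 to 100578535 ranked 423 and 1017 at Day10 and 69144 and 77058 at Day3, and was listed at Day0 in replicate 2 alone, at rank 162413. The region on chromosome 4 from 114636887 to 114637387 ranked 723 and 752 at Day10, 88335 and 101856 at Day3, and 159717 and 150269 at Day0. The region on chromosome 5 from 150175001 to 150175501 ranked 589 and 947, and that on chromosome 17 from 48136052 to 48136552 ranked 444 and 1248, both absent from the Day0 lists. The 4 others were covered by strong Day0 peaks, as on chromosome 14 from 55828328 to 55828828, where peaks ranked 200 and 529 at Day0 overlapped the window.

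The 10 lost regions named by the fixed rule were all covered at Day10 by peaks with a summit elsewhere. On chromosome 19, the window from 11942597 to 11943097 ranked 143 and 42 at Day0 and was covered at Day10 by peaks ranked 63 and 389. On chromosome 1, the window from 72294134 to 72294634 ranked 444 and 750 at Day0 and 30 and 56 at Day3, and was covered at Day10 by peaks ranked 6795 and 6344. Among lost regions that passed both rules, named after their values were seen, the strongest lay on chromosome 16 from 97482333 to 97482833. It ranked 1822 and 2050 at Day0, 9986 and 17501 at Day3, and 108430 and 100802 at Day10. On chromosome 5, the region from 136598938 to 136599438 ranked 2160 and 2154 at Day0, 23401 and 13707 at Day3, and 142466 and 157392 at Day10. Another, on chromosome 1 from 14554689 to 14555189, ranked 2569 and 2351 at Day0, 28084 and 21637 at Day3, and 304104 and 311443 at Day10. The region on chromosome 19 from 41924318 to 41924818 ranked 3451 and 2905 at Day0 and still 4959 and 6891 at Day3, and 122159 and 101253 at Day10.

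**Figure D3:**
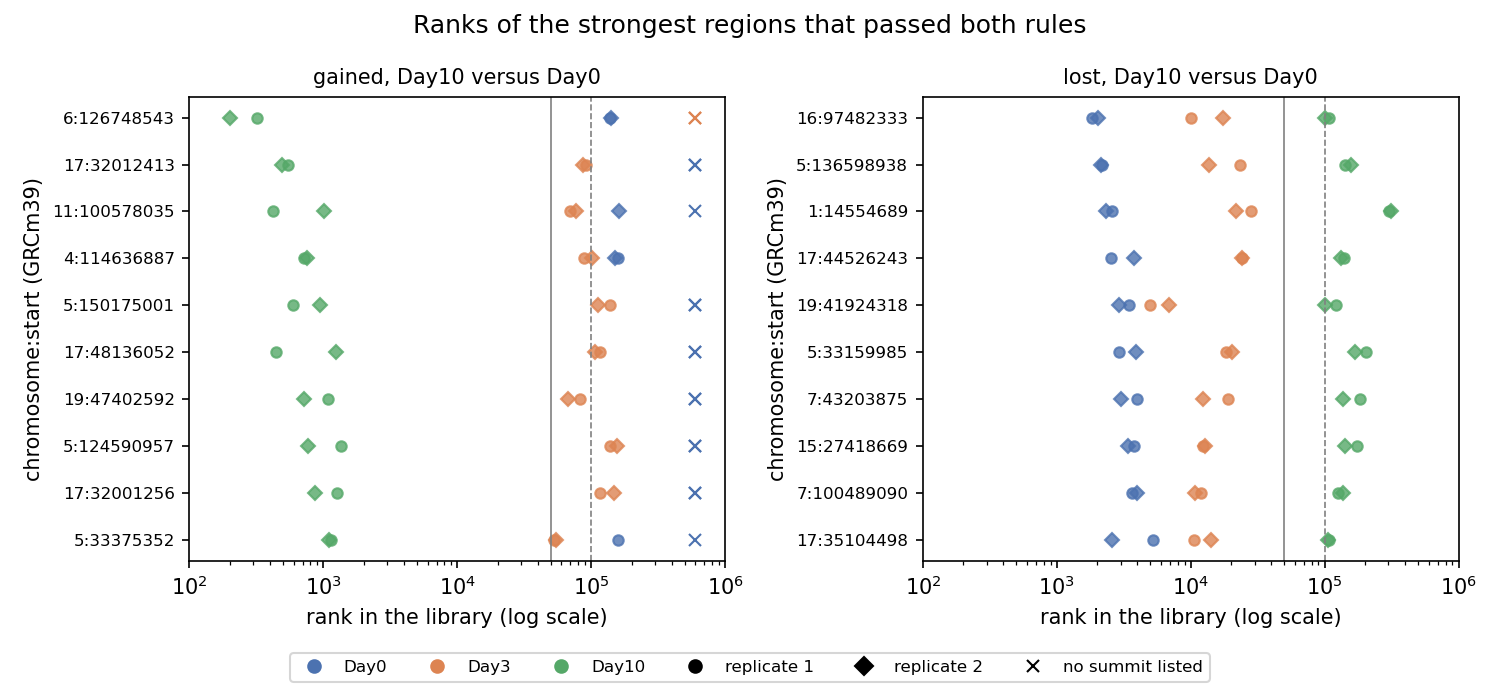
Rank in each of the 6 libraries (x axis, log scale) of the 10 gained and the 10 lost regions with the best ranks among those that passed both rules for Day10 versus Day0, by chromosome and start. Solid and dashed lines mark ranks 50000 and 100000 and crosses mark libraries with no summit listed in the window; the gained region on chromosome 6 ranks 319 and 200 at Day10, and the lost region on chromosome 16 ranks 1822 and 2050 at Day0.

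Of the gained regions that passed both rules, 25.7% and 26.0% were listed in the Day0 libraries. Of the lost regions, 80.2% and 81.2% were still listed in the Day10 libraries. Over all lost regions, with those not listed placed last, the median rank was 177509 and 177276 there. The Day10 lists are more than 2 times as long, which by itself raises the share listed.

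Day10 was compared with Day3 for the later part of the time course. By the summit rule 7143 regions were gained, 3616 were lost and 29800 were kept, and the other splits gave 53 to 72 regions. Regions that passed both rules numbered 6078 gained and 2489 lost, against 0 in the other splits under the overlap rule. The gained regions outnumbered the lost by 1.98 times under the summit rule. Without a gap between ranks there were 12798 gained and 12198 lost, but in that setting the counts nearly balance by construction.

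Of the 10 gained regions named by the fixed rule, 2 passed both rules, the regions on chromosomes 5 and 17 starting at 150175001 and 48136052 that were also gained against Day0. The region ranked first lay on chromosome 17 from 40154098 to 40154598. It ranked 12 and 14 at Day10 and was covered by a peak ranked 8 and 9 at Day3. The second, on chromosome 11 from 117186831 to 117187331, ranked 58 and 163 at Day10 and was covered by peaks ranked 4451 and 3996 at Day3, while at Day0 it held summits at ranks 78785 and 72641. Among the regions that passed both rules, named after their values were seen, a region on chromosome 14 from 25867177 to 25867677 ranked 1701 and 1217 at Day10. Another on chromosome 11 from 113112087 to 113112587 ranked 1035 and 2757. Neither had a listed peak in any Day0 or Day3 library. The region on chromosome 5 from 124590957 to 124591457 ranked 1350 and 769 at Day10, and 137587 and 155159 at Day3. None of the 10 lost regions named by the rule passed both rules, and the first was the window on chromosome 1 described for Day10 versus Day0. The strongest lost region that passed both rules was the one on chromosome 19 starting at 41924318. A region on chromosome 2 from 32575763 to 32576263 ranked 10110 and 9955 at Day3 and 163478 and 126359 at Day10. A region on chromosome 5 from 88851365 to 88851865 ranked 15928 and 9504 at Day3 and 203317 and 237025 at Day10.

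**Figure D4:**
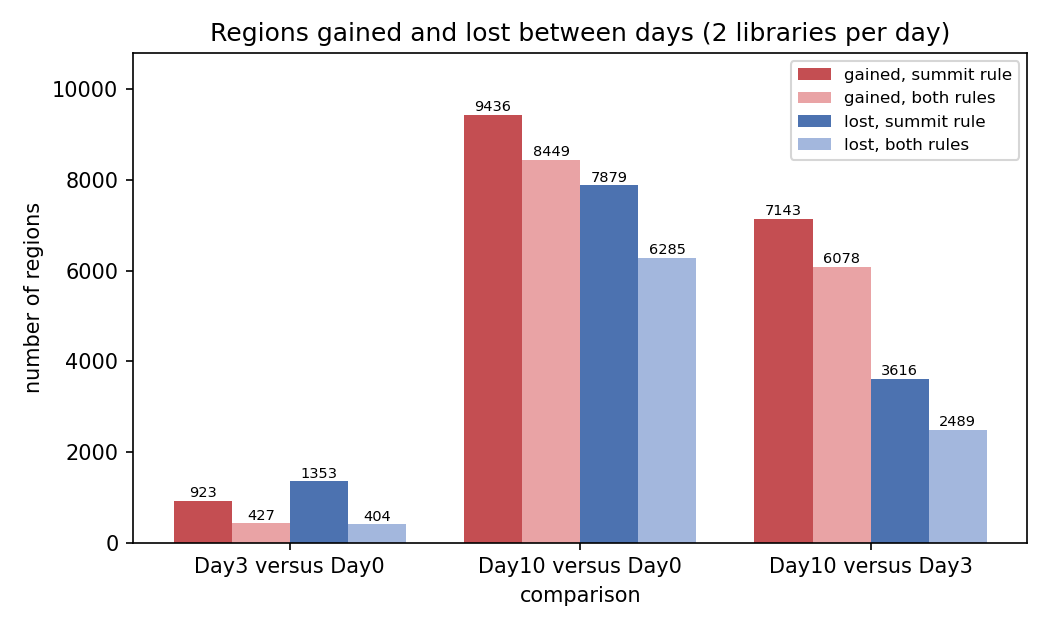
Number of regions gained and lost in each comparison (y axis), by the summit rule and by both rules together. Day10 versus Day0 has 9436 gained and 7879 lost regions by the summit rule, and Day3 versus Day0 has 923 and 1353.

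Across all 3 days, most regions gained by Day10 were still out of the 100000 strongest at Day3. Being out does not mean that no peak was listed. Of the regions gained at Day10 against Day3 under both rules, 37.0% and 36.4% were listed in the Day3 libraries. The classes thus follow rank cutoffs and do not give the time at which a region first opened. By the summit rule, 6172 regions were out of the 100000 strongest on Day0 and Day3 and within the 50000 strongest at Day10, 2726 passed through an intermediate class at Day3, and 538 were already strong at Day3. Of regions strong at Day0 and out at Day10, 2784 were still strong at Day3, 4297 were intermediate and 798 were already out. The intermediate class includes regions on which the Day3 libraries differed. Without Day3 replicate 1 it held 3539 of the lost regions, with 3272 still strong and 1068 already out, and without Day3 replicate 2 it held 3513, with 3237 and 1129. Regions strong on all days numbered 25716. In the 8 pairings in which no pair came from a single day, no pattern of change exceeded 155 regions. Those pairings can only place regions in a pattern of change when libraries of the same day disagree. Over all 14 other pairings and orders, the intermediate classes reached at most 664. The patterns that part a single day from the others cannot be tested this way, since pairings that keep that day together give the same regions.

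Regions strong at Day3 alone numbered 135, and regions weak at Day3 alone numbered 277. Under the overlap rule these fell to 23 and 16, so few regions were transient once any overlapping peak was counted. Leaving out 1 library removes a condition, so it can only raise these counts. Without Day3 replicate 1 they were 281 and 507, and without Day3 replicate 2 they were 253 and 505. Without Day0 replicate 1 the first was 218, and without Day0 replicate 2 it was 223.

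The state at Day3, by the overlap rule, was then taken for the regions that changed by Day10 under both rules. Of 8449 gained regions, 3.5% were within the 50000 strongest in both Day3 libraries, 30.2% were intermediate and 66.3% were out. Of 6285 lost regions, 32.9% were still strong at Day3, 61.6% were intermediate and 5.6% were out. Lost regions start in a bounded class and gained regions in an open one, so the cutoffs alone can part these shares and the 2 directions are not compared. To measure how far a library outside the selection moves toward intermediate ranks, a choice was made with 1 Day0 library held back. This choice used the overlap rule alone. Among 9220 gained regions chosen on Day0 replicate 1 and Day10, 4.2% were at rank 100000 or better in the held-back Day0 replicate 2, against 32.9% and 32.6% in the Day3 libraries. Among 7195 lost regions chosen in the same way, 11.6% were worse than rank 50000 in the held-back library, against 64.8% and 64.6% in the Day3 libraries. Holding back Day0 replicate 1 gave 4.7% for gained and 12.0% for lost regions.

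Many regions called at Day3 were called again at Day10. Of the 427 regions gained at Day3 under both rules, 273 were gained at Day10, and of the 404 lost at Day3, 351 were lost at Day10. The rule does not allow opposite calls against the same Day0 libraries. Independent lists of these sizes would share 45.8 gained and 32.3 lost regions of all 78698. Among the 11500 regions whose Day0 ranks allow a gain and the 45651 that allow a loss, a count added after the overlap was seen, they would share 313.7 and 55.6. The 273 shared gains lie below the first of these, but that comparison cannot decide whether gains recur. Regions whose Day0 ranks allow a gain entered the set only through the strongest peaks of a Day3 or Day10 library. Of these 11500 regions, 73.5% were called gained at Day10, which by itself raises the 313.7. Neither an excess nor a lack of shared gains is therefore read from it. The 55.6 takes every allowed region as equally likely to be lost by Day10. Regions lost at Day3 had median Day0 ranks of 42467 and 43241. By the overlap rule, 27.44% of the last Day0 rank class were lost by Day10 against 0.31% of the first, so rank alone raises this number. Simulated unchanged groups shared 0.0 on average. The rule called almost no region in those groups, so the 0.0 does not measure what the shared Day0 libraries add. Both comparisons use the same Day0 libraries, which cannot be split with 2 libraries in each part. Part of the excess for lost regions may thus come from the shared controls, and part from rank.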

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

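Peaks outside chromosomes 1 to 19, X and Y took no part in the comparisons. They numbered 322 and 300 in the Day0 libraries, 326 and 312 in the Day3 libraries, and 454 and 423 in the Day10 libraries. Day3 replicate 1, with 326, and both Day10 libraries lay above the higher Day0 library. As a share of the list they were 0.196% and 0.182% at Day0, 0.183% and 0.176% at Day3, and 0.119% and 0.108% at Day10, so the share did not rise. In every library 1 of these peaks spanned 16299 bases of the mitochondrial genome.

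The tests in the next 2 paragraphs were chosen after the results were seen. The Day10 lists were 2.32 and 2.37 times as long as the mean Day0 list. Thinning the recovered summit pileups to the Day0 depth left 253176 and 259054 peaks, or 1.54 and 1.57 times the Day0 list, so depth may account for a large part of the difference. The thinning uses summits that were chosen at full depth, which raises the number left, so whether depth accounts for the rest cannot be told apart from a change with differentiation. Separate handling of the Day10 libraries also stays open. Their smallest listed widths were 68 and 72 bases, below every other library, and names inside their lists show another storage path than those of the other 4 lists. Both properties follow the day exactly. The names inside the Day3 lists alone hold the word lysis, so a separate handling at Day3 is open as well.

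The calls at Day3 by the summit rule may in large part reflect summits that moved within peaks listed on both days. Of the 2276 regions gained or lost, 57.3% were covered by one of the 50000 strongest peaks in both libraries of the other day. As the whole cause it is argued against: no peak at rank 100000 or better overlapped 831 of these regions (36.5%) in either library of the other day, nor 14734 of the 17315 regions called for Day10 versus Day0 (85.1%). A change with the day stays open for these, as does the separate handling above. Whether the covering peak is the same peak on both days was not tested, nor whether the summit shifts follow differentiation.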

How the results depend on the processing

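The alternatives were fixed before the data were examined, except the order of ties, the 1-base overlap rule, both rules together, and leaving out libraries for the time course and list lengths. Of the alternative values, 160 stayed within 1.5 times the first value or on the same side, 66 moved further and 9 changed direction. The cause was not tested except where the setting itself changes how many peaks enter. Ranking by fold gave the same order and tests nothing, though its values are counted among the 160. Ties in random order moved no count by 1.5 times. Comparing 25000 peaks, excluded to 50000, gave 432 gained and 695 lost regions for Day3 versus Day0, 4280 and 3922 for Day10 versus Day0, and 3392 and 1801 for Day10 versus Day3. With 75000, excluded to 150000, there were 1749 and 2329, then 14573 gained, then 10817 and 5710. With no gap the counts were 6798 and 7040, 15155 and 15324 (a difference of -169, which reversed), and 12798 and 12198. Equal numbers of peaks per library make gained and lost counts nearly balance without a gap, so this setting cannot test their balance. A wider gap gave 599 gained at Day3, 5079 lost for Day10 versus Day0 and 2012 lost for Day10 versus Day3. Presence in the full lists gave 25188 and 22002 (a reversed difference of 3186), 155161 and 24105, and 138200 and 14880, where longer lists alone add gained regions. A -log10 q of 5 gave 13812 and 24429, 83563 and 29350, and 78894 and 14395.

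For Day3 versus Day0 the balance also changed with the form of the region. Merged intervals gave 415 and 405 (gained minus lost 10), overlap of at least 50% of the window 1861 gained (13 more than lost), the 1-base rule 477 and 416 (61 more), and both rules 427 and 404 (23 more). The 50% rule shared only 367 of the 923 gained and 344 of the 1353 lost regions of the summit rule, so it called mostly other regions. For the Day10 comparisons the counts of gained and of lost regions stayed within 1.5 times in these settings, while gained minus lost for Day10 versus Day0 went from 1557 to between 2151 and 3451. Leaving out 1 library gave 1328 to 1400 gained and 1858 to 2093 lost regions at Day3. The transient patterns ranged from 184 to 281 up and from 346 to 507 down. With 1 library left out fewer conditions had to be met, so counts of changed regions and of transient patterns could only rise by construction.

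Replicate numbers did not pair the libraries: the correlations of replicate deviations across days were 0.013, 0.007 and 0.001. With the replicate block the counts were 3729 and 5041 for Day3 versus Day0, 15730 and 16359 for Day10 versus Day0 (a difference of -629, reversed), and 13020 and 10616 for Day10 versus Day3. This rule asks for a 2-fold deeper rank within each pair in place of rank 100000.

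List lengths of Day10 over Day0 were 1.52 at a -log10 q of 5 and 1.47 at 10, and those of Day3 over Day0 reversed to 0.9 and 0.94. For the time course, 25000 peaks gave 197 early gained, 1107 gained in steps, 2976 late gained, 437 early lost, 2171 lost in steps, 1314 late lost and 115 transient down. The 1-base rule gave 331 early gained, 355 early lost, 23 transient up and 16 transient down. The mean Jaccard index of the same-day pairs was 0.788 to 0.856 under the alternatives, and the pairing by day ranked first in each. Alternatives for promoter shares, gene lists, motifs and repeats were not run, since no annotation or genome of the build was used here. In simulated data built on the Day0 pileups, the rule called 40.1% of 4-fold gains for Day10 versus Day0. How far this holds for the real Day10 lists, and what depth alone limits, was not tested.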

Other observations

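Some of the regions gained, and some of those lost, at Day10 were gathered in parts of the genome. All tests in this part were chosen after the changed regions were seen, except that the bounds for the copy number test were written before its result. Under both rules, 29 of 1744 bins of 1 megabase held more regions gained against Day0 than chance at an adjusted p of 0.05, and they held 519 of the 8449 gained regions. The bin on chromosome 11 from 113000001 to 114000000 stood first, with 44 gained and 3 lost among 109 regions, where 11.7 gained were expected (hypergeometric test, exact, adjusted p = 1.8e-12). Against Day3 the same bin held 37 gained and 1 lost (exact hypergeometric test, adjusted p = 7.1e-12). The bin on chromosome 8 from 115000001 held 23 gained of 56 (exact test, adjusted p = 3.9e-06). The bins starting at 73000001 on chromosome 1, 133000001 on chromosome 2 and 142000001 on chromosome 7 held 26 of 83, 10 of 16 and 20 of 57. For lost regions 10 bins passed, with 107 of 6285 regions, and the difference from gained regions was not tested. At an unadjusted p under 0.05 there were 165 bins for gained and 159 for lost regions. The first bin for lost regions was on chromosome 6 from 36000001, with 11 lost and 0 gained among 23 regions (exact test, adjusted p = 8.0e-04). At Day3 no bin passed in either direction (hypergeometric test), with 427 gained and 404 lost regions to place, and 38 and 25 bins had an unadjusted p under 0.05. Neighbouring regions are not independent, so these p-values describe the libraries and are too small.

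Shares also differed between chromosomes. Chromosome 3 had 7.92% of its regions gained and 11.07% lost at Day10 against Day0, where all chromosomes together had 10.74% and 7.99% (Fisher's exact test across regions, adjusted p = 1.4e-06 and 1.3e-08). Gained shares were also lower on chromosomes 7 and X, at 8.66% and 7.59%, and higher on chromosomes 5, 6 and 17, at 12.54%, 12.18% and 12.27% (exact test, adjusted p of 2.3e-02 or less for each). Lost shares were lower on chromosomes 8 and 11, at 6.64% and 5.78%, and higher on chromosomes 13 and 18, at 9.9% and 9.83% (exact test, adjusted p of 3.1e-02 or less for each). Base composition was not analysed here, as no genome sequence of the build was used.

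An added copy, on 2 copies, of the 29 bins in all Day10 cells is 1 candidate explanation of the gathered gains. It would lift kept regions there as well. The 491 kept regions of these bins moved up in rank by a median of 0.2 on the log2 scale beyond all kept regions (95% bootstrap interval over bins 0.06 to 0.31). A 1.5-fold higher pileup would give 1.27, or 1.04 when the saturation of the pileup is allowed for, a correction added after the first result. The interval lies below 0.52, the bound that follows from the lower value, which argues against an added copy in all cells as the whole cause, although 1 bin did reach the shift of 1.04. A copy gained in part of the cells, base composition and regulation shared by neighbouring regions stay open.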
